A study of Mus musculus with 12 samples.

How the data were processed

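The measurements were genome-wide RNA levels of mouse splenic CD8+ T cells, on 12 arrays in 4 groups of 3. Per the labels, spleen cells of C57BL/6 mice were depleted of other cell types with a CD8a+ T Cell Isolation Kit, treated for 6 h, and lysed for total RNA with an RNeasy kit; the RNA was labelled with biotin through a WT Plus kit. The labels number the replicates but give no day, batch or animal, so the replicate arrays may be technical repeats, and the p-values below measure the spread between these samples. Groups were taken from the labels.

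The deposited values were on a log scale, taken as log2, with each row centred by the authors on its median over the 12 arrays, so that levels were removed (largest absolute row median 5e-07). The deposited log2 values ran from -4.55 to 3.31. The log base is not given in the sources used here. Base 10 was excluded because the decimal steps of the values show that many rows stood at 8 or above before centring, which a 16-bit scanner cannot give in base 10; a natural log was not excluded, and in that case every printed fold would be larger. A higher value was read as more RNA. The between-array normalization, the summarization of probes and the software are not given in the sources used here. The array medians were -0.0157 to 0.0165. Arrays give no count depth; their number limits the precision, and signal over background could not be assessed on centred values.

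The file held 33793 rows. The platform's probe table gave 1 gene symbol to 23521 rows, several symbols to 1814 and none to 8458. The rows with 1 symbol covered 22180 genes, which were all tested. For the 1082 genes with several rows, the row with the highest mean over the 12 arrays was used. On centred values that mean does not rank rows by level. It reflects how a row's values lie around their median, so the choice can depend on the changes themselves. With the mean of a gene's rows instead, 2 called results of named genes lost their call. Gene symbols were checked against the Entrez identifiers of the RefSeq annotation of GRCm38.p6, where 21994 were found, all with the same symbol. Genes are therefore named by symbol and, for leading genes, Entrez identifier; values summarise probes over whole transcripts, and no positions are given.

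Groups were compared with limma 3.58.1 in R 4.3.3: a mean per group over all 12 arrays, contrasts, and moderated two-sided tests (8 residual and 5.09 prior degrees of freedom). Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within each of 5 comparisons: IFN-4a in resting cells, IFN-4a in stimulated cells, anti-CD3 without and with IFN-4a, and the interaction, which is the IFN-4a change in stimulated cells minus that in resting cells. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over 105 tests (21 lists in 5 comparisons), beside camera with an estimated correlation and fry, which tests whether a set moves on balance in 1 direction without comparing it with other genes. Of 44 list calls, 23 were lost with an estimated correlation. Median, mean and test pointed in different directions only for lists that were not called: cytotoxic effectors and coinhibitory genes with IFN-4a in both states, ligands of NK cell receptors in resting cells and the interaction, cell cycle in resting cells, with anti-CD3 alone and in the interaction, glycolysis with IFN-4a in stimulated cells, MHC class I with anti-CD3 and IFN-4a, apoptosis in the interaction, and some of the marker lists. The IFN-4a changes in both states were compared by Pearson and Spearman correlation across genes, without a p-value because genes are not independent replicates.

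The comparisons, tests, gene lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule took, per comparison, the 10 largest called changes in each direction with no overlap between the arrays of both groups (a condition that did not apply to the interaction), passing over predicted genes, small RNAs and receptor segments; the 4 members of each list with the largest absolute change; the check genes Ifit1, Isg15, Mx1, Irf7, Cd69, Il2ra, Nr4a1, Egr2, Cd8a, Cd8b1 and Cd3e; and every measured ligand of NK cell receptors. By chance 10% of unchanged genes show no overlap between 3 and 3 arrays. The 21 lists were antiviral interferon-stimulated genes, interferon signalling and feedback, MHC class I antigen presentation, ligands of NK cell receptors, cytotoxic effectors, T cell cytokines and chemokines, early T cell activation, coinhibitory receptors and ligands, T cell quiescence and homing, memory and effector transcription factors, ribosome biogenesis, glycolysis and nutrient uptake, cell cycle, apoptosis, T cell receptor signalling, and markers of B cells, CD4 T cells, NK cells, monocytes with macrophages and dendritic cells, granulocytes, and erythroid cells with platelets. Of their 397 entries 355 were measured, 2 of them through another symbol. Lck, Tcf7, H2-D1 and the Raet1 genes were among those not measured, of which 19 occurred only in rows of several symbols. Families of near-identical genes may cross-hybridise.

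Alternatives were the replicate number as a block, quantile normalization of the centred values, centring of each array on its median, all rows of the file, the mean of a gene's rows, array weights, only the 2 groups compared, an adjusted p under 0.01, an absolute log2 change of at least 1, and each array left out in turn. Chosen after seeing the data were a robust variance without trend, and a restriction to the 6080 genes (8001 rows, 23.7%) whose decimals show them at 8 or above on their 6 highest arrays before centring. Some dim rows pass that restriction by chance. A filter on levels and a variance trend on levels could not be run on centred values. All 12 arrays were used.

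The fit was tested on simulated data of the same size with known changes. It recovered 91%, 94%, 87% and 93% of changes of 0.5 on the log2 scale in the 4 pairwise comparisons, in the order given above, and 62% in the interaction; at 1 it recovered 100% in the pairwise comparisons and 98% in the interaction. False calls made up 2.55%, 7.18%, 2.60%, 7.21% and 1.23% of the calls. In the list test a shifted set was found, and of 20 unshifted sets 1 passed at an unadjusted 0.05.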

Results

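Genome-wide RNA levels were measured on 12 single-channel microarrays of mouse CD8+ T cells. The cells came from the spleens of C57BL/6 mice and were enriched by removing other cell types. They were kept for 6 h with an antibody against CD3, which engages the T cell receptor complex, or with phosphate-buffered saline (PBS) as mock treatment. Each condition was run with and without IFN-4a, the interferon of this series on type I interferon. The 4 groups of 3 arrays were PBS, PBS with IFN-4a, anti-CD3, and anti-CD3 with IFN-4a. Cells given PBS are called resting and cells given anti-CD3 stimulated. Values were on a log scale taken as log2 and were centred per probe set, so a value of 0 is that probe set's median over the 12 arrays and no absolute level can be read. The array medians lay between -0.0157 and 0.0165. The number of arrays limits the precision, and p-values measure only the spread between these samples, which may be technical. The lowest correlation between arrays of the same group was 0.730 across probe sets, and the highest between arrays of different groups was 0.535. The first principal component held 62.4% of the variance, the next 21.7% and the third 3.23%. Each fold change below compares 3 arrays with 3 arrays, SE is its standard error, and adjusted p comes from the moderated test of limma over 22180 genes.

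The first comparison asked how resting cells respond to IFN-4a. Genes of the antiviral interferon response rose most. Cxcl10 (Entrez gene 15945), which encodes a chemokine that attracts activated T cells, rose 37.7-fold (log2 5.24, SE 0.09, adjusted p = 1.64e-13). Ifit1 (Entrez gene 15957), which encodes a protein that binds viral RNA, rose 35.7-fold (adjusted p = 2.71e-14), and Mx1 (Entrez gene 17857), which encodes an antiviral GTPase, rose 18.7-fold. The decreases were smaller. Ubash3b (Entrez gene 72828), a phosphatase gene that restrains T cell receptor signalling, fell 2.06-fold (log2 -1.05, SE 0.08, adjusted p = 9.01e-07).

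In resting cells IFN-4a changed 2753 of 22180 genes, 930 higher and 1823 lower. The median change was 0.385 on the log2 scale among raised genes and -0.324 among lowered genes. At least 2-fold changes were seen in 179 raised and 2 lowered genes. Leaving out the second PBS with IFN-4a array reduced the count to 1721, with 1058 lower, and quantile normalization reduced the lowered genes to 1189. Among the 10 largest increases were also Oasl2 at 5.19 and Oas2 at 4.86, of the oligoadenylate synthetase family, Usp18 at 4.76, which encodes a brake on interferon receptor signalling, and Cmpk2 at 4.59. The paralogs Trim30c at 5.02 and Slfn5 at 4.71 belong to families with near-identical members, whose probes may cross-hybridise. Other large decreases were Clybl at -0.98, Slc26a11 at -0.92, Sgsh at -0.90, a lysosomal sulfatase gene, Arrb1 at -0.83, which encodes beta-arrestin, and Vkorc1 at -0.82, which encodes the enzyme that recycles vitamin K.

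Of 27 measured antiviral interferon-stimulated genes, 26 rose and none fell (27 higher when adjusted over the list alone, camera adjusted p = 3.74e-84). Of 16 genes of interferon signalling and feedback, 8 rose (8 adjusted over the list alone, adjusted p = 2.78e-10), with Irf7 at 3.43, a transcription factor of interferon genes, and Stat2 at 2.20 and Irf9 at 1.76, which bind DNA together downstream of the type I interferon receptor. In the MHC class I presentation list 14 of 19 genes rose (16 adjusted over the list alone, adjusted p = 3.24e-18). Examples were Nlrc5 at 1.54, the transactivator of MHC class I genes, Psmb10 at 1.13, an immunoproteasome subunit gene, and Tapbp at 0.97, the tapasin gene. In the apoptosis list 9 of 19 rose and 2 fell, with the same counts adjusted over the list alone (adjusted p = 1.54e-06). Its largest changes were Pml at 2.09 and Daxx at 2.04, genes of nuclear body proteins, and Casp4 at 1.59 and Casp1 at 0.69, genes of inflammatory caspases. These calls of all 4 lists were kept with an estimated correlation.

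Several T cell lists moved less. In the cytokine list 3 of 20 genes rose (5 adjusted over the list alone, adjusted p = 0.00335), Cxcl10 being by far the largest. The Ccl4 call (log2 0.50) ended under quantile normalization (log2 -0.36) and with only the 2 groups compared (adjusted p = 0.0974). The Csf1 call (log2 0.45) ended without the second PBS with IFN-4a array (adjusted p = 0.0815) and without the second PBS array (adjusted p = 0.0794). The list had adjusted p = 0.288 with an estimated correlation, and under quantile normalization it pointed the other way (adjusted p = 0.396). In the early activation list 5 of 26 rose and 1 fell, the same numbers adjusted over the list alone (adjusted p = 0.00333; adjusted p = 0.278 with an estimated correlation), and this too turned under quantile normalization (adjusted p = 0.333). Its examples were Cd69 at 1.16, an early surface marker, Rel at 0.54, a gene of an NF-kappaB subunit, and Il2ra at 0.98, the interleukin-2 receptor alpha chain gene, whose call ended under quantile normalization (log2 0.13). In ribosome biogenesis 11 of 22 genes fell and none rose (15 lower adjusted over the list alone, adjusted p = 1.81e-07; adjusted p = 0.0743 with an estimated correlation), with Utp20 at -0.42, Noc3l at -0.41 and Wdr12 at -0.39. In glycolysis and nutrient uptake 8 of 19 fell and 1 rose (9 and 1 adjusted over the list alone, adjusted p = 0.0304; adjusted p = 0.381 with an estimated correlation), and the call ended without the second PBS array (adjusted p = 0.0747), without the third PBS with IFN-4a array (adjusted p = 0.0594) and among bright genes alone, those at 8 or above on their 6 highest arrays before centring.

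In T cell quiescence and homing 4 of 18 fell and 1 rose (7 and 1 adjusted over the list alone, adjusted p = 0.0282; adjusted p = 0.268 with an estimated correlation), with Id3 at -0.52 and S1pr1 at -0.37, the receptor for exit from lymphoid organs. That call ended under quantile normalization (adjusted p = 0.396), without the second PBS array (adjusted p = 0.0550) and among bright genes alone. Of the memory and effector transcription factors 4 of 12 rose, as many adjusted over the list alone (adjusted p = 0.00327; adjusted p = 0.0900 with an estimated correlation), with Bcl6 at 0.66, a repressor gene, and Id2 at 0.38. Cytotoxic effectors went both ways, with 4 of 17 higher and 3 lower (6 and 3 adjusted over the list alone, adjusted p = 0.295, median -0.07 with a mean above 0). The granzyme genes Gzma at 2.28 and Gzmb at 1.33 and Tnfsf10 at 1.68, the TRAIL gene, rose. Coinhibitory genes also went both ways, with 5 of 16 higher and 2 lower (5 and 4 adjusted over the list alone, adjusted p = 0.306, median -0.05 with a mean above 0). There Cd274 at 2.25, the PD-L1 gene, and Lgals9 at 1.26, the galectin-9 gene, rose, and Cd5 at -0.53 fell.

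Ligands of NK cell receptors did not pass camera as a list in resting cells (2 of 14 higher and 3 lower, 3 and 3 adjusted over the list alone, camera adjusted p = 0.720). The list did pass fry (adjusted p = 0.0278). The 14 measured ligands did not include the Raet1 genes or H60a. Icam1, an adhesion ligand gene, rose by 0.90 and Cd47, which encodes a signal against engulfment, by 0.48. Vim fell by 0.51, Pvr by 0.31 and Cd48 by 0.26. The Pvr call was lost without the second PBS with IFN-4a array (log2 -0.25, adjusted p = 0.0586) and the Cd48 call under quantile normalization (log2 -0.23). Clec2d stood at 0.28 (adjusted p = 0.0611), H60b at -0.13, and H60c, Ulbp1, Clec2g, Clec2i, Nectin2, Cd70 and Cfp lay between -0.05 and 0.06, none past the threshold. The cell cycle list had 2 of 22 higher and 3 lower, as adjusted over the list alone (adjusted p = 0.986), with Ccnd2 at 1.47, the cyclin D2 gene, and Cdk2 at -0.36. T cell receptor signalling had 4 of 22 lower and none higher (4 lower and 2 higher adjusted over the list alone, adjusted p = 0.306), among them Lat at -0.35 and Plcg1 at -0.34. Of the check genes not yet given, Isg15 rose by 3.48. Nr4a1 stood at -0.07, Egr2 at 0.16, Cd8a at 0.14, Cd8b1 at 0.05 and Cd3e at -0.01, none past the threshold, and Egr2 turned under quantile normalization (log2 -0.34). Marker lists of B cells, CD4 T cells, NK cells, myeloid cells, granulocytes, and erythroid cells and platelets had adjusted p from 0.158 to 0.928.

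**Figure D1:**
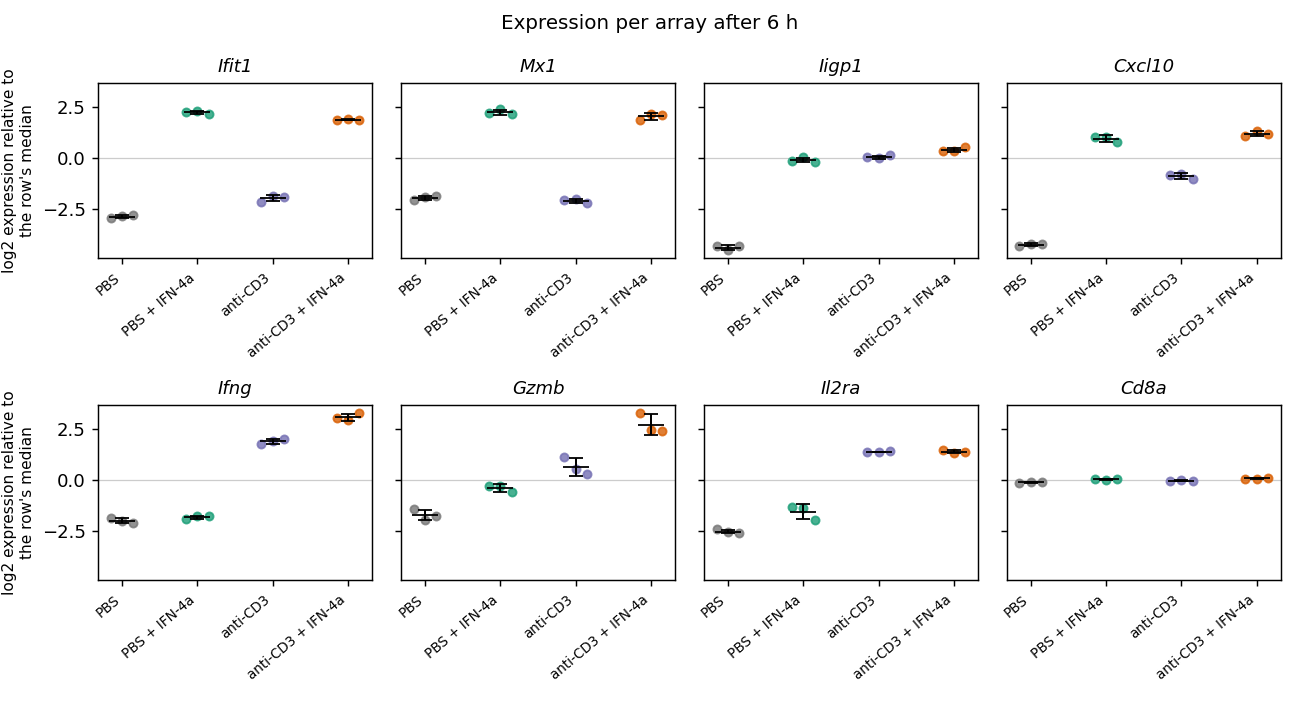
Expression of 8 genes on each of the 12 arrays after 6 h, as log2 relative to the median of the probe set over all arrays, with 1 point per array, grouped by treatment, and bars for the mean ± SD (n = 3). Ifit1 and Mx1 were high in both groups with IFN-4a, Iigp1 was high in 3 of the 4 groups, Ifng was highest with anti-CD3 and IFN-4a, Cd8a differed little, and the rise of Ifit1 with anti-CD3 alone turned to a fall under quantile normalization (log2 -0.22).

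The next comparison asked what IFN-4a changes in cells stimulated through CD3. Antiviral genes again rose most. Mx2 (Entrez gene 17858), which encodes an antiviral GTPase, rose 21.1-fold (log2 4.40, SE 0.10, adjusted p = 4.42e-12), and Ifit1 rose 14.7-fold. Ifng (Entrez gene 15978), which encodes interferon gamma, rose 2.27-fold (log2 1.18, SE 0.09, adjusted p = 1.83e-06), and Gzmb (Entrez gene 14939), the granzyme B gene, rose 4.23-fold (SE 0.24 on the log2 scale, adjusted p = 9.84e-05). The largest decrease was Cyp2s1, a cytochrome P450 gene, which fell 1.72-fold (log2 -0.79, adjusted p = 0.00250).

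In stimulated cells IFN-4a changed 760 genes, 442 higher and 318 lower, with median changes of 0.534 and -0.318. At least 2-fold changes were seen in 116 raised genes and in no lowered gene. The count depended on single arrays. It was 484 without the second anti-CD3 array and also without the third anti-CD3 with IFN-4a array, and 503 without the third anti-CD3 array. The lowered genes numbered 149 without the third and 134 without the first anti-CD3 with IFN-4a array, and 137 without the second and 119 without the third anti-CD3 array. The balance of directions turned with array weights (625 higher and 726 lower) and among bright genes alone (414 higher and 582 lower). Other large increases were Trim30c at 5.01, Slfn5 at 4.27, Mx1 at 4.15, Oas2 at 4.11, Rsad2 at 4.10, the viperin gene, Oasl1 at 4.04 and Ifi204 at 4.19, the last from a family of near-identical genes. Decreases included Sgsh at -0.77, Abcg3 at -0.72, Pltp at -0.69, a gene of phospholipid transfer, and Itgb7 at -0.61, an integrin chain gene of gut homing.

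Of 27 antiviral genes, 26 rose (27 adjusted over the list alone, adjusted p = 2.36e-112), a call kept with an estimated correlation. In interferon signalling and feedback 4 of 16 rose, as many adjusted over the list alone (adjusted p = 7.33e-05; adjusted p = 0.0954 with an estimated correlation): Usp18 by 3.47, Irf7 by 2.32, Stat2 by 1.53 and Irf9 by 0.66. In MHC class I presentation 7 of 19 rose (10 adjusted over the list alone, adjusted p = 2.47e-08; adjusted p = 0.0743 with an estimated correlation), with Psmb10 at 0.70, Nlrc5 at 0.53 and Psmb8 at 0.46. In the apoptosis list 5 of 19 rose and none fell (6 adjusted over the list alone, adjusted p = 2.21e-08), a call kept with an estimated correlation, with Daxx at 2.05, Pml at 1.43, Casp4 at 0.69 and Casp8 at 0.64. In the cytokine list 4 of 20 rose, as many adjusted over the list alone (adjusted p = 5.20e-05; adjusted p = 0.170 with an estimated correlation): Cxcl10 by 2.09, Lif by 1.26, Ifng by 1.18 and Il3 by 1.03. Of the memory and effector transcription factors 3 of 12 rose (4 higher and 1 lower adjusted over the list alone, adjusted p = 0.0188; adjusted p = 0.170 with an estimated correlation): Tbx21 by 0.52 and Eomes by 0.46, T-box genes of effector CD8+ T cells, and Id2 by 0.46. This call ended with array weights (adjusted p = 0.0616), without the second anti-CD3 with IFN-4a array (adjusted p = 0.0915) and without the first anti-CD3 array (adjusted p = 0.106).

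Cytotoxic effectors had 5 of 17 higher and none lower, as adjusted over the list alone, but the list did not pass its test (adjusted p = 0.0608, median -0.03 with a mean above 0). Gzma rose by 1.95, Tnfsf10 by 1.24 and Gzmc by 0.83. NK cell markers passed (2 of 9 higher, as adjusted over the list alone, adjusted p = 0.0188; adjusted p = 0.172 with an estimated correlation, and 0.103 without the first anti-CD3 with IFN-4a array), and the call ended among bright genes alone. The raised members were Gzma and Nkg7, cytotoxic granule genes that the cytotoxic list also holds, and Nkg7 (log2 0.24, adjusted p = 0.0286) lost its call when any array of the anti-CD3 or anti-CD3 with IFN-4a groups was left out (highest adjusted p 0.123, without the third anti-CD3 array). No gene of ribosome biogenesis passed the threshold, and none did adjusted over the list alone, while the list of 22 tested lower (median -0.09, adjusted p = 0.00535; adjusted p = 0.288 with an estimated correlation, and 0.0535 in the preset test without the second anti-CD3 array), a call that also ended among bright genes alone.

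Early activation genes did not pass in stimulated cells (0 of 26 higher, 2 adjusted over the list alone, adjusted p = 0.908), with Cd69 at 0.31 and Il2ra at 0.01, neither past the threshold. Coinhibitory genes had 2 of 16 higher, as adjusted over the list alone (adjusted p = 0.950, median -0.04 with a mean above 0), with Lgals9 at 1.15. Quiescence and homing had 2 of 18 higher (2 higher and 1 lower adjusted over the list alone, adjusted p = 0.928). Glycolysis and nutrient uptake had 2 of 19 higher and 1 lower, as adjusted over the list alone (adjusted p = 0.951), with Hk1 at 0.52, a hexokinase gene. The cell cycle list had 1 higher and 1 lower of 22 (4 and 1 adjusted over the list alone, adjusted p = 0.951). T cell receptor signalling had none of 22 (2 lower adjusted over the list alone, adjusted p = 0.183). Of 14 ligands of NK cell receptors 1 rose and 1 fell (3 and 2 adjusted over the list alone, adjusted p = 0.665): Cd47 rose by 0.60 and Ulbp1, a ligand gene of the receptor NKG2D, fell by 0.31 (adjusted p = 0.0357), a call lost with only the 2 groups in the fit (adjusted p = 0.116) and without several single arrays (adjusted p up to 0.154, without the third anti-CD3 array; also without the second anti-CD3, first and the third anti-CD3 with IFN-4a, and first and second PBS with IFN-4a arrays). Isg15 rose by 3.26. The other marker lists had adjusted p from 0.220 to 0.951.

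The comparison of anti-CD3 with PBS, both without IFN-4a, asked what stimulation changes by itself. Genes of secreted chemokines and cytokines were among the largest increases. Ccl3 (Entrez gene 20302), an inflammatory chemokine gene, rose 120-fold (log2 6.91, SE 0.22, adjusted p = 3.31e-11), Xcl1 (Entrez gene 16963), which encodes a chemokine for cross-presenting dendritic cells, rose 48.0-fold, and Ifng rose 15.2-fold. Iigp1 (Entrez gene 60440), an interferon-inducible GTPase gene, rose 22.1-fold without added IFN-4a. The largest decrease was St8sia6 (Entrez gene 241230), a sialyltransferase gene, which fell 5.21-fold (log2 -2.38, SE 0.18, adjusted p = 1.81e-07).

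Anti-CD3 without IFN-4a changed 6992 genes, 3018 higher and 3974 lower, with median changes of 0.507 and -0.390. At least 2-fold changes were seen in 562 raised and 150 lowered genes. Large increases also included Rgs16 at 4.89, a regulator of G protein signalling, Ccl4 at 4.76, Sema7a at 4.45, Tnfsf14 at 4.33, the LIGHT gene, Tnfrsf9 at 4.32, which encodes the costimulatory receptor 4-1BB, Tnf at 4.31 and Nr4a2 at 4.20, an orphan nuclear receptor gene. Large decreases also included Cpm at -1.91, a carboxypeptidase gene, Slc6a19 at -1.85, an amino acid transporter gene, Rasgrp2 at -1.67, an activator of small GTPases, and Sesn1 at -1.59, a sestrin gene.

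In the cytokine list 15 of 20 rose and 3 fell, as adjusted over the list alone (adjusted p = 7.49e-12). In early activation 21 of 26 rose and 2 fell (22 and 2 adjusted over the list alone, adjusted p = 1.55e-21), with Il2ra at 3.93, Nr4a3 at 3.54, Nr4a1 at 3.44, Egr2 at 3.24 and Cd69 at 2.02. All 22 genes of ribosome biogenesis rose, as adjusted over the list alone (adjusted p = 8.45e-29), with Polr1b at 2.22, an RNA polymerase I subunit gene, and Nop2 at 2.22. In glycolysis and nutrient uptake 14 of 19 rose and 2 fell, as adjusted over the list alone (adjusted p = 1.52e-11), with Slc7a5 at 2.51, an amino acid transporter gene, Hk2 at 2.37, a hexokinase gene, and Tfrc at 2.34, the transferrin receptor gene. Coinhibitory genes rose, 10 of 16 with 2 lower (11 and 2 adjusted over the list alone, adjusted p = 4.84e-07): Cd160 by 3.62, Cd274 by 3.27 and Pdcd1, the PD-1 gene, by 2.49. Quiescence and homing genes fell, 14 of 18 with 2 higher (15 and 2 adjusted over the list alone, adjusted p = 7.56e-07): S1pr1 stood at -1.28, Tob1, an antiproliferative gene, at -1.09, and Lef1 at -0.92. These 6 calls were kept with an estimated correlation.

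Other lists passed with the preset correlation and not with an estimated one. Antiviral genes had 18 of 27 higher and 1 lower (19 and 2 adjusted over the list alone, adjusted p = 3.06e-10; adjusted p = 0.0572 with an estimated correlation), and the list turned lower under quantile normalization (adjusted p = 0.0690). Oasl2 rose by 2.21, Zbp1, a nucleic acid sensor gene, by 1.71 and Bst2, the tetherin gene, by 1.41. Ifit1 at 0.91, Irf7 at 0.89 and Isg15 at 0.56 turned under quantile normalization, to -0.22, -0.11 and -0.36, and Mx1 stood at -0.14 (adjusted p = 0.303). MHC class I presentation had 12 of 19 higher and 2 lower, as adjusted over the list alone (adjusted p = 2.68e-06; adjusted p = 0.118 with an estimated correlation), with Erap1 at 1.15, a peptide-trimming enzyme gene, and Nlrc5 at 1.08. Cytotoxic effectors had 9 of 17 higher and 1 lower (9 and 2 adjusted over the list alone, adjusted p = 0.000131; adjusted p = 0.0743 with an estimated correlation), with Gzmb at 2.37 and Serpinb9 at 1.79, which encodes an inhibitor of granzyme B. Apoptosis genes had 12 of 19 higher and 5 lower, as adjusted over the list alone (adjusted p = 0.000530, and 0.0588 with an estimated correlation). Among them were Bcl2a1a at 1.44, a survival gene with near-identical copies, and Bcl2 at 0.88 in 1 of its 2 probe sets and 0.26 in the other. Memory and effector transcription factors had 5 of 12 higher and 3 lower (7 and 3 adjusted over the list alone, adjusted p = 0.0304; adjusted p = 0.193 with an estimated correlation, and 0.0535 in the preset test without the second anti-CD3 array), with Tbx21 at 2.08 and Eomes at 1.59. The apoptosis and transcription factor calls also ended among bright genes alone.

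Interferon signalling and feedback had 8 of 16 higher and 6 lower with anti-CD3 alone, as adjusted over the list alone (adjusted p = 0.0884), with Ptpn6 at 1.15, a phosphatase gene, and Irf1 at 1.14, an interferon-responsive transcription factor. The cell cycle list had 8 of 22 higher and 4 lower (9 and 6 adjusted over the list alone, adjusted p = 0.105, median -0.02 with a mean above 0), with Cdkn1a at 2.71 and Cdkn1b at -1.17, genes of cell cycle inhibitors, and Ccnd2 at 1.78. T cell receptor signalling had 9 of 22 higher and 6 lower, as adjusted over the list alone (adjusted p = 0.158), with Zap70 at 0.93, a kinase gene of the receptor, and Themis at -0.87. Ligands of NK cell receptors had 1 of 14 higher and 5 lower, as adjusted over the list alone (adjusted p = 0.306). Vim fell by 0.72, Cd48 by 0.70, Cd47 and Clec2i by 0.54. H60b fell by 0.52 (adjusted p = 0.0254), a call lost under quantile normalization (adjusted p = 0.0549) and without the first or the third anti-CD3 or the second or the third PBS array (adjusted p up to 0.113, without the second PBS array). Icam1 rose by 0.24 (adjusted p = 0.0269), lost without any single anti-CD3 array or without the second or the third PBS array (adjusted p up to 0.0870, without the second anti-CD3 array). Cd8b1 fell by 0.34, and Cd8a at 0.08 and Cd3e at 0.01 did not pass. The 6 marker lists of other cells had adjusted p from 0.813 to 0.951.

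**Figure D2:**
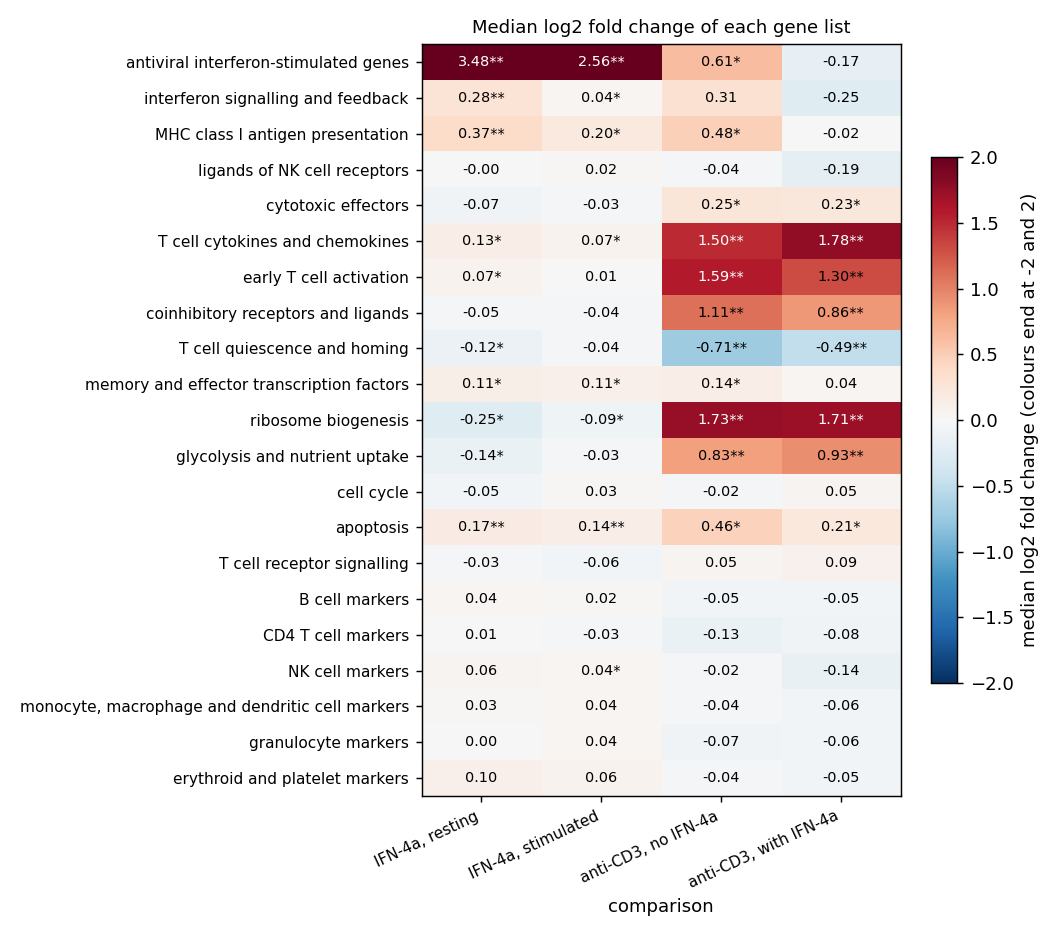
Median log2 fold change of the measured members of 21 gene lists in 4 comparisons (colour scale from -2 to 2, printed values exact to 2 decimals), with 1 star for camera adjusted p under 0.05 and a second star where the call was kept with an estimated correlation. Antiviral genes rose with IFN-4a in both states (3.48 and 2.56) and ribosome biogenesis with anti-CD3 (1.73 and 1.71), while under quantile normalization the antiviral list with anti-CD3 alone and the cytokine and early activation lists with IFN-4a in resting cells took the opposite direction.

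The comparison of anti-CD3 with PBS, both with IFN-4a, asked the same question in the presence of interferon. Ccl3 rose 76.2-fold (log2 6.25, SE 0.22, adjusted p = 8.17e-11), Ifng rose 30.8-fold (log2 4.94, SE 0.09, adjusted p = 4.88e-13) and Gzmb rose 8.75-fold. St8sia6 fell most, 4.21-fold (log2 -2.07). Most antiviral genes did not rise further: Ifit1 stood at -0.36, Mx1 at -0.21, not past the threshold, and Isg15 at 0.34 (adjusted p = 0.0563).

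With IFN-4a present anti-CD3 changed 6017 genes, 2774 higher and 3243 lower, with median changes of 0.544 and -0.387. At least 2-fold changes were seen in 577 raised and 69 lowered genes. Large increases also included Xcl1 at 5.19, Rgs16 at 4.68, Sema7a at 4.51, Ccl4 at 4.36, Tnfsf14 at 4.32, Crtam at 4.24, an adhesion receptor gene of cytotoxic cells, Tnf at 4.22 and Tnfrsf9 at 4.19. Large decreases also included Cpm at -1.79, Gria3 at -1.61, a glutamate receptor subunit gene, Cd55 at -1.35, a complement regulator gene, and Cd7 at -1.34.

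The lists with the clearest changes were those that also moved without IFN-4a. Cytokines had 14 of 20 higher and 3 lower (15 and 3 adjusted over the list alone, adjusted p = 1.01e-11), and early activation 21 of 26 higher and 2 lower (22 and 2 adjusted over the list alone, adjusted p = 7.73e-22), with Nr4a2 at 4.11, Nr4a1 at 3.52, Il2ra at 2.95, Egr2 at 2.97 and Cd69 at 1.16. All 22 ribosome biogenesis genes rose, as adjusted over the list alone (adjusted p = 1.02e-32), with Polr1b at 2.49 and Nop2 at 2.46. Glycolysis and nutrient uptake had 15 of 19 higher and 1 lower (15 and 2 adjusted over the list alone, adjusted p = 2.29e-14), with Tfrc at 2.82 and Slc7a5 at 2.61. Coinhibitory genes had 11 of 16 higher and 1 lower, as adjusted over the list alone (adjusted p = 7.50e-08), with Cd160 at 3.34, Pdcd1 at 2.67 and Cd5 at 1.48. Quiescence and homing had 15 of 18 lower and 1 higher, as adjusted over the list alone (adjusted p = 6.16e-07), with S1pr1 at -1.05 and Klf3 at -0.92, while Id3 rose 2.14-fold. These 6 calls were kept with an estimated correlation. Cytotoxic effectors had 8 of 17 higher and 2 lower (9 and 3 adjusted over the list alone, adjusted p = 0.000214; adjusted p = 0.0792 with an estimated correlation), with Serpinb6b at 1.99 and Prf1 at 1.69, the perforin gene. Apoptosis genes had 9 of 19 higher and 4 lower, as adjusted over the list alone (adjusted p = 0.00327; adjusted p = 0.0900 with an estimated correlation), with Tnfrsf10b at 1.12, a death receptor gene; the call also ended among bright genes alone.

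The remaining lists did not pass with IFN-4a present. Antiviral genes had 2 of 27 higher and 10 lower (3 and 13 adjusted over the list alone, adjusted p = 0.0662), with Ifitm3 at 1.51, which encodes a membrane protein that blocks viral entry, as the largest rise and Ifit2 at -0.45 as the largest fall. Interferon signalling and feedback had 3 of 16 higher and 9 lower (4 and 9 adjusted over the list alone, adjusted p = 0.113), with Ifnar1 at -0.62, a chain of the type I interferon receptor, and Stat4 at -0.48. MHC class I presentation had 5 higher and 3 lower of 19, as adjusted over the list alone (adjusted p = 0.345, median -0.02 with a mean above 0), with Canx at 0.74, the calnexin gene. Memory and effector transcription factors had 4 of 12 higher and 2 lower, as adjusted over the list alone (adjusted p = 0.0662), with Tbx21 at 2.20 and Eomes at 2.02. Cell cycle genes had 8 of 22 higher and 4 lower (9 and 5 adjusted over the list alone, adjusted p = 0.0526), with Cdk4 at 1.23, and T cell receptor signalling had 8 of 22 higher and 5 lower (10 and 5 adjusted over the list alone, adjusted p = 0.0885), with Cd6 at 0.96. Ligands of NK cell receptors had 1 of 14 higher and 6 lower, as adjusted over the list alone (adjusted p = 0.0863): Pvr rose by 0.36, Cd48 fell by 0.53, Clec2i by 0.46, Icam1 and Vim by 0.45, Cd47 by 0.42 and Ulbp1 by 0.30. The 6 marker lists had adjusted p from 0.784 to 0.948.

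The last comparison tested whether the response to IFN-4a differed between stimulated and resting cells. Many interferon-inducible genes responded less in stimulated cells. Iigp1 had the largest difference (interaction -3.96 on the log2 scale, SE 0.11, adjusted p = 2.94e-10), with group values of -4.42 ± 0.11 with PBS, -0.10 ± 0.12 with PBS and IFN-4a, 0.04 ± 0.07 with anti-CD3 and 0.40 ± 0.11 with both (SD, n = 3). Some genes responded more. Ifng had group values of -2.01 ± 0.11, -1.85 ± 0.08, 1.92 ± 0.12 and 3.10 ± 0.18 in the same order (interaction 1.01, SE 0.13, adjusted p = 0.00122), and Ifitm3 (Entrez gene 66141) an interaction of 1.33 (adjusted p = 5.03e-06).

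The response to IFN-4a differed in 202 genes, 62 with a higher and 140 with a lower change in stimulated cells, with median differences of 0.523 and -0.782. Of the 62 genes 46 were lowered by IFN-4a in resting cells. For these a higher change means that the fall was weaker, absent or reversed in stimulated cells. Across genes, which are not independent replicates, the IFN-4a changes in the 2 states had Pearson r 0.762 and Spearman rho 0.463. IFN-4a raised 369 genes in both states (18.5 if independent) and lowered 207 in both (26.1 if independent), and 3 genes were called in opposite directions. Of the 442 genes raised in stimulated cells 426 were also above 0 in resting cells, and of the 318 lowered 300 were below 0. The count of genes with a different response was 118 under quantile normalization, with 70 lower. Among bright genes alone it was 393, with 193 higher and 200 lower, and with array weights 289, with 117 higher and 172 lower. The 62 genes with a higher change numbered between 30 and 40 without the first, second or the third anti-CD3 array, the second anti-CD3 with IFN-4a array, the first or second PBS with IFN-4a array, or the second or the third PBS array, at 32, 36, 40, 31, 37, 30, 34 and 36 in that order.

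Among the higher changes in stimulated cells were also Lif at 1.19 and Il3 at 0.89, cytokine genes, Ier3 at 0.79, a stress-response gene, and Hspa1b at 1.25, a heat shock protein gene with a near-identical copy. The smaller responses included Gbp10 at -2.56, Gbp5 at -2.45, Igtp at -2.34 and Irgm1 at -2.07, genes of interferon-inducible GTPases with close paralogs, Cxcl10 at -3.14 and Cd274 at -2.24. Antiviral genes responded less as a list, 16 of 27 lower and 1 higher (17 and 1 adjusted over the list alone, adjusted p = 4.27e-35), with Oasl2 at -2.31, Rtp4 at -2.06 and Zbp1 at -1.82. Mx1 at -0.07 and Isg15 at -0.23 did not pass, and Ifit1 at -1.28 and Irf7 at -1.11 lost their calls under quantile normalization (log2 -0.31 and -0.27). In interferon signalling and feedback 6 of 16 were lower (8 adjusted over the list alone, adjusted p = 2.98e-11), with Irf1 at -0.77 as an example, and in MHC class I presentation 6 of 19 (12 adjusted over the list alone, adjusted p = 2.40e-14), with Nlrc5 at -1.01. These 3 calls were kept with an estimated correlation.

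Early activation genes responded less, 3 of 26 lower (6 adjusted over the list alone, adjusted p = 0.00107; adjusted p = 0.243 with an estimated correlation), but the list turned under quantile normalization (adjusted p = 0.801) and was lost with fry (adjusted p = 0.0764). All 3 called members lost their calls under quantile normalization: Cd69 at -0.85 (log2 -0.44 there), Il2ra at -0.97 (log2 -0.30 there) and Rel (log2 -0.34 there, adjusted p = 0.103). The Il2ra call was also lost in 9 of 12 fits without a single array (adjusted p up to 0.0717, without the second PBS with IFN-4a array). It was kept without the first anti-CD3 with IFN-4a, the third PBS with IFN-4a and first PBS arrays. Ribosome biogenesis tested higher with no member past the threshold among 22 (2 adjusted over the list alone, adjusted p = 5.67e-05; adjusted p = 0.161 with an estimated correlation). Glycolysis and nutrient uptake tested higher with 1 of 19, Tfrc at 0.48 (2 adjusted over the list alone, adjusted p = 0.00740; adjusted p = 0.288 with an estimated correlation), lost with array weights (adjusted p = 0.0616) and without the second anti-CD3 with IFN-4a array (adjusted p = 0.0848). Quiescence and homing tested higher with 1 of 18, Id3 at 0.51 (2 adjusted over the list alone, adjusted p = 0.0120; adjusted p = 0.227 with an estimated correlation), lost under quantile normalization (list adjusted p = 0.105, Id3 adjusted p = 0.0561), without the third anti-CD3 with IFN-4a array (list adjusted p = 0.0800) and among bright genes alone.

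The other lists did not pass, and larger or smaller here gives the sign of the interaction only. Cytokines had 3 of 20 with a larger and 1 with a smaller response, as adjusted over the list alone (adjusted p = 0.951), and tested in the other direction under quantile normalization (adjusted p = 0.000384). Cytotoxic effectors had 1 larger and 1 smaller of 17 (1 and 2 adjusted over the list alone, adjusted p = 0.928). Coinhibitory genes had 1 smaller of 16, Cd274 (1 larger and 2 smaller adjusted over the list alone, adjusted p = 0.163). Memory and effector transcription factors had 1 smaller of 12, Bcl6 at -0.92 (1 smaller and 1 larger adjusted over the list alone, adjusted p = 0.589), and cell cycle 1 of 22, as adjusted over the list alone, Ccnd2 at -1.25 (adjusted p = 0.950). Apoptosis had 2 of 19 smaller (5 smaller and 2 larger adjusted over the list alone, adjusted p = 0.101), and both calls, Casp4 at -0.90 and Pml at -0.65, were lost under quantile normalization (adjusted p = 0.124 and 0.341). T cell receptor signalling had none of 22, also adjusted over the list alone (adjusted p = 0.932). Ligands of NK cell receptors had 1 of 14 smaller, Icam1 at -0.69 (2 adjusted over the list alone, adjusted p = 0.988). The 6 marker lists had adjusted p from 0.484 to 0.950.

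**Figure D3:**
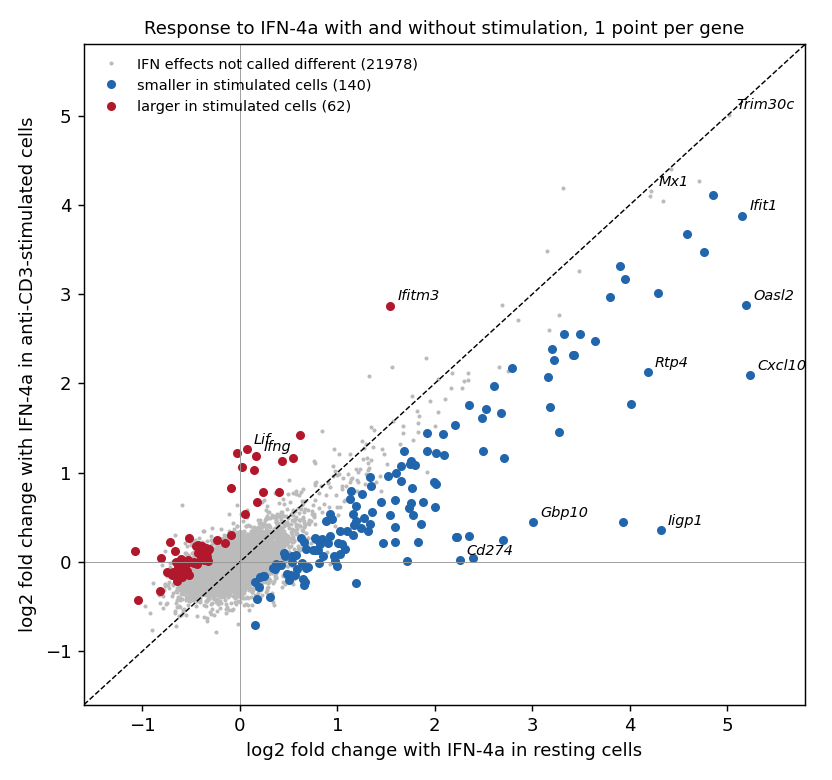
Log2 fold change with IFN-4a in resting cells (horizontal axis) against that in anti-CD3-stimulated cells (vertical axis), with 1 point per gene and a dashed line for equal changes. The 140 genes with a lower change in stimulated cells are blue and the 62 with a higher change are red. Of the 62 genes 46 were lowered by IFN-4a in resting cells. Iigp1 (4.32 against 0.36) lies far under the line.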

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

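Tests chosen only after the result was seen were the split count with additive effects removed, the share of genes also raised by anti-CD3 alone and the test of the GTPase family. The response to IFN-4a differed between stimulated and resting cells in the test of the difference itself. The change was higher in stimulated cells for 62 genes and lower for 140. Of the 62 genes 46 were lowered by IFN-4a in resting cells, so a higher change was mostly not a larger response. The largest positive differences on the log2 scale were Ifitm3 at 1.33, Hspa1b at 1.25, Lif at 1.19, Lipg at 1.04, Ifng at 1.01, Vmn1r20 at 0.94, Gzmc at 0.92, Il3 at 0.89, Mpeg1 at 0.80 and Ier3 at 0.79. The largest negative ones were Iigp1 at -3.96, Cxcl10 at -3.14, Gbp10 at -2.56, Gbp5 at -2.45, Igtp at -2.34, Oasl2 at -2.31, H2-T24 at -2.24, Cd274 at -2.24, Irgm1 at -2.07 and Rtp4 at -2.06. Mpeg1 and Vmn1r20 lost their calls under quantile normalization (adjusted p = 0.139 and 0.0652) and in 9 and 10 of the 12 fits without a single array; Mpeg1 reached an adjusted p of 0.109 without the second anti-CD3 array and kept its call without the first anti-CD3 with IFN-4a, the third PBS with IFN-4a and second PBS arrays, and Vmn1r20 reached 0.0927 without the first PBS with IFN-4a array and kept its call without the second anti-CD3 and second PBS arrays. The replicate block also ended the Vmn1r20 call. Gzmc lost its call without the second PBS with IFN-4a array (adjusted p = 0.0570) and without the second PBS array (adjusted p = 0.0526).

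Whole lists differed in the same test, given as the median difference of their members on the log2 scale. It was -0.77 for antiviral genes, -0.30 for interferon signalling and feedback, -0.28 for MHC class I presentation, -0.10 for early activation, 0.0824 for quiescence and homing, 0.19 for ribosome biogenesis and 0.11 for glycolysis and nutrient uptake. With an estimated correlation 4 of these calls were lost: early activation (adjusted p = 0.243), quiescence and homing (0.227), ribosome biogenesis (0.161) and glycolysis and nutrient uptake (0.288). The early activation list took the opposite direction under quantile normalization (adjusted p = 0.801). Rows that the probe table gives no gene symbol, or several, were outside the comparisons and also held called changes: 565 with IFN-4a in resting cells, 109 with IFN-4a in stimulated cells, 1644 with anti-CD3 alone, 1343 with anti-CD3 in the presence of IFN-4a and 44 in the interaction, of 10272 such rows tested.

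The first pattern is the lower change with IFN-4a of 140 genes in stimulated cells, 136 of which IFN-4a raised in resting cells. Of 100 splits within both arms (drawn from 200), 7 gave at least the real 202 genes and the highest other gave 3260, so this count does not exclude chance. All 6 others were among the 19 drawn splits that kept 1 arm whole, in which the IFN-4a effect of that arm becomes a difference by construction. Splits mixing both arms gave at most 0, but they put the IFN-4a effects into the spread within groups, so this says nothing about chance. With the additive effects removed 1 of 100 splits, the real one, reached 202 and the highest other gave 34. This argues against chance, but only in a test chosen after the planned one had failed to exclude it. Saturated probes cannot be told apart from a true limit: 5.71% of the 140 genes (8, 95% interval 2.5% to 10.9%) were bounded under 14 on the original scale, and centring hides the level of the other 132, so the bound set for this test could not be read. Of the 140 genes 127 were also raised by anti-CD3 alone, 90.7% (95% interval 84.6% to 94.96%). The share was 28.1% of the 794 other genes that IFN-4a raised in resting cells and at most 38.2% in 20 simulations with additive effects. But the difference is the anti-CD3 change with IFN-4a minus the one without, and pairing these at random across genes gave 94.1% to 100%. The share therefore cannot tell whether a rise with anti-CD3 limited the response. All groups were taken at 6 h, so no order in time is known. The 127 genes differed between both IFN-4a groups by a median of 0.0455, the 13 others by -0.47, and 75 of the 127 still rose with IFN-4a in stimulated cells. With quantile normalization 61 of 70 such genes were also raised by anti-CD3 alone and 108 of the 140 stayed above 0. With array centring the numbers were 125 of 136 and 136 of 140.

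The second pattern is that IFN-4a lowered more genes than it raised in resting cells, 1823 against 930, a ratio of 1.96; the excess depended on the threshold, with 793 against 531 at an adjusted p under 0.01 (1.49) and 2 against 179 at 2-fold. A difference in scaling between the arrays cannot be told apart: centring each array on its median shifted every change by only -0.00723 and so could not decide (1928 against 872, 2.21), and quantile normalization brought the ratio to 1.55 (1189 against 766). Dim rows are argued against, since the ratio was 2.59 among genes at 8 or above on their 6 highest arrays (1668 against 644). A complete loss of the effect in stimulated cells is argued against by direction. There 87.5% of the lowered genes (1596, 95% interval 85.9% to 89.0%) were below 0, against 50.9% of all genes. A weaker effect is not argued against, since their median was -0.12 there against -0.32 in resting cells, with 207 called lower there. In the main fit the excess itself was absent in stimulated cells, with 442 genes raised and 318 lowered. The authors' own normalization stays open, 46 of the 1823 genes had a called difference between states, and no biological explanation beyond the IFN-4a treatment was tested.

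The third pattern is the family of guanylate-binding proteins and immunity-related GTPases, of which 16 were measured, a set chosen after its values were seen. Of the 13 raised by IFN-4a in resting cells 12 responded less in stimulated cells, against 124 of 917 other raised genes; the two-sided Fisher's exact p of 7.09e-10 cannot support an enrichment, since the set was chosen for these genes and paralogs are not independent. With anti-CD3 alone 13 rose and 1 fell; the median change was 2.12 with anti-CD3 alone, 2.01 with IFN-4a in resting cells, 0.26 with IFN-4a in stimulated cells and 0.16 with anti-CD3 in the presence of IFN-4a. With quantile normalization 13 rose with anti-CD3 alone and 11 responded less, and with array centring 13 and 12. Cross-hybridisation between paralogs stays open. A candidate explanation that was not tested is that interferon gamma made by stimulated cells also raised these genes.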

How the results depend on the processing

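Of 372 called results of named genes, 59 lost their direction or call under at least 1 alternative run, as did 23 of 44 list calls. Of 207 results of named genes that were not called, 44 changed under at least 1 alternative run, as did 22 of 61 list results not called. With fry 20 of those list results passed. The restriction to bright genes and the robust variance were chosen after seeing the data; a filter on levels and a variance trend were not run, since centred values hold no levels, and for the same reason signal over background could not limit any call. The replicate block gave 2848, 866, 7025, 6126 and 207 genes and changed no list call; it ended 5 and added 11 calls of named genes. Equal replicate numbers were not taken as pairs, since not every pair correlated above 0.1 (18 pairs, r -0.0754 to 0.265), but 9 of 12 arrays correlated most with 1 of their own number, so a weak link stays open.

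Under quantile normalization, which forces equal tails on the centred values, lowered genes in resting cells numbered 1189 and the interaction 118, with 70 lower. There Ccl3 (-0.596), Ccl4 (-0.364), Cdkn1a (-0.0305) and Egr2 (-0.341) reversed for IFN-4a in resting cells, and Ifit1 (-0.225), Irf7 (-0.110) and Isg15 (-0.355) for anti-CD3 alone. So did the lists of cytokines (adjusted p = 0.396) and early activation (0.333) with IFN-4a in resting cells, antiviral genes with anti-CD3 alone (0.0690), and cytokines (0.000384) and early activation (0.801) in the interaction. Array weights gave 1351 genes for IFN-4a in stimulated cells, 726 lower, and 117 higher in the interaction; only the 2 groups compared gave 172 lower for IFN-4a in stimulated cells. The cause was not tested for these settings. Before quantile normalization the tails differed by group. The lowest values were -4.36, -4.55 and -4.36 on the PBS arrays and -2.25, -2.27 and -1.29 with anti-CD3 and IFN-4a. Forcing the tails equal can by itself shift strongly changed genes. A turn under quantile normalization alone therefore cannot tell a weak change from an effect of the method.

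Stricter thresholds call fewer genes by construction. An adjusted p under 0.01 gave 1324 genes for IFN-4a in resting cells (531 higher, 793 lower), 402 in stimulated cells (90 lower) and 115 for the interaction (18 higher). An absolute log2 change of at least 1 gave 181 (179 higher, 2 lower), 116 (116 higher, 0 lower), 712 (562 and 150), 646 (577 and 69) and 47 (6 and 41) in the order of the comparisons. Bright genes alone gave 582 lowered with IFN-4a in stimulated cells, 4623 changed with anti-CD3 alone (2390 lower) and 393 in the interaction (193 higher), with r 0.858 and rho 0.523 between both IFN-4a responses; the cause was not tested for the rises.

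Leaving out each array gave 1721 to 2910 genes for IFN-4a in resting cells (663 to 1000 higher, 1058 to 1910 lower), 484 to 748 in stimulated cells (335 to 431, 119 to 317), 6123 to 7066 for anti-CD3 alone (2705 to 3044, 3417 to 4022), 5507 to 6097 with IFN-4a (2547 to 2789, 2854 to 3315) and 137 to 198 for the interaction (30 to 58, 107 to 140), with r 0.723 to 0.782 and rho 0.356 to 0.555. The arrays that moved a count by over 1.5 times were the second PBS with IFN-4a array (1721, 1058 lower), the third (484, 149 lower) and first (134 lower) anti-CD3 with IFN-4a arrays, and the second (484, 137 lower) and the third (503, 119 lower) anti-CD3 arrays. Genes higher in the interaction numbered 32, 36 and 40 without the first, second and the third anti-CD3 array, 31 without the second anti-CD3 with IFN-4a array, 37 and 30 without the first and second PBS with IFN-4a array, and 34 and 36 without the second and the third PBS array.

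Other splits of the arrays bear on the 4 pairwise counts. Each has 10 splits of 6 arrays, too few for a share under 0.05; 1 of 10, the real one, reached 2753, 760, 6992 and 6017 genes, and the highest other gave 0.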

Other observations

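Markers of other cell types did not pass camera as lists, apart from the NK cell markers with IFN-4a in stimulated cells. That call was lost with an estimated correlation (adjusted p = 0.172), without the first anti-CD3 with IFN-4a array (adjusted p = 0.103) and among bright genes alone. With IFN-4a in resting cells, markers of NK cells (fry adjusted p = 0.0352) and of erythroid cells and platelets (fry adjusted p = 0.0358) passed fry. Single members did change. Cd40lg, a gene of activated CD4 T cells that activated CD8+ T cells also express, rose by 1.04 with anti-CD3 alone and by 0.74 with IFN-4a present. Cd79b, a B cell receptor gene, fell by 0.69 and 0.43 in the same comparisons. Cd209a, a dendritic cell gene, fell by 1.01 and 0.64 in 1 of its 2 probe sets only; the other stood at -0.0465 and 0.156, and with the mean of both the call in the presence of IFN-4a was lost (adjusted p = 0.134). Itgax, an integrin gene that activated T cells also express, rose by 0.56 and 0.41. Fcgr3, an Fc receptor gene of NK cells and macrophages, fell by 0.89 and 0.49.

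The test of whether changes with IFN-4a and with anti-CD3 go together beyond the shared PBS arrays was chosen before its result was seen. In resting cells genes lowered by IFN-4a were often also lowered by anti-CD3 alone: 952 genes fell in both, against 327 if independent, and 299 rose in both, against 117, among 22102 genes outside the interferon lists and 16 GTPase family genes, a family chosen after its values were seen. Both comparisons share the PBS arrays, which by itself makes their changes go together. The covariance of the log2 changes across these genes was 0.0178, against a mean of 0.00348 and a highest of 0.00372 in 100 simulations with the shared arrays alone, a difference of 0.0143; with the lists alone removed it was 0.0211 (highest simulated 0.00381), with 952 and 312 genes. The correlation across genes was 0.19, lower than the 0.50 of the simulations, in which the changes themselves are small. The simulations drew independent noise for each gene from the spread within groups, so a deviation common to all PBS arrays was not in them. The higher covariance therefore cannot tell an overlap of both responses from such a deviation. An overlap remains a hypothesis, and the authors' normalization was not tested as a source of the covariance.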
